A study of Drosophila melanogaster with 4 samples.

How the data were processed

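H3K36me1 was measured by ChIP-seq in heads of adult Oregon-R flies raised in population cages, with heads separated from whole flies by sieving, per the labels' protocols. The tissue was homogenized and treated with formaldehyde, and chromatin was sheared by sonication before precipitation. The sex of the flies is not given in the sources used here. There were 2 ChIP samples and 2 input samples, grouped and numbered by their titles. Per the labels, each input served the cluster list of the ChIP replicate of the same number. Inputs entered no comparison of their own.

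Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Per the file headers, cluster positions refer to FlyBase release 5 of the genome, and starts and ends count from 1. The authors deposited a list of enriched clusters for each ChIP replicate and a list for the set of replicates, named the combined list here. Each cluster carries a score deposited by the authors, a positive number without a stated unit. What the score is relative to, the cluster caller, its threshold and filters, and the way the replicates were combined are not given in the sources used here. Scores were therefore used to describe, rank and filter clusters within a list, as differences and never as folds. Between lists, scores themselves were set against each other only in a correlation over overlapping clusters. Score differences within lists were also averaged over the replicates or given as a range over lists. The narrowest cluster measured 1302 bases in replicate 1, 1301 bases in replicate 2 and 1001 bases in the combined list. Whether a filter removed narrower regions is not stated. The lists give no read counts. The depth is unknown, and a region outside a list did not pass the authors' threshold or filters at that depth and is not shown to lack the mark.

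Clusters were compared by position with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A cluster was called found in the other replicate if at least 1 base was shared. The Wilson 95% interval was computed over clusters. Chance overlap came from 1000 circular shifts of the other list within each arm, with a 1-sided p for higher overlap. Covered percentages used the sequence lengths of the file headers. The large autosomal arms are 2L, 2R, 3L and 3R, and the heterochromatic scaffolds are 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet. Replicates were averaged as mean ± SD with n = 2, and values of the combined list have no SD. Clusters were paired one to one where each overlapped a single cluster of the other list, and correlations over pairs and over 1 Mb windows had 2-sided permutation p-values from 100000 permutations. The X label was permuted over 1 Mb windows as many times. Intervals for the score differences came from 1000 bootstrap samples of windows. Telomeric and centromeric ends of arms follow the release 5 orientation, in which X, 2L and 3L run towards the centromere and 2R and 3R away from it.

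The named regions follow a rule fixed in advance: without annotation of the build of the lists, the 10 widest clusters found in both replicates are named by coordinates. The rule was applied to the stretches of bases that a cluster of replicate 1 shares with a cluster of replicate 2, ranked by shared width. A wide cluster shared only in part can therefore go unnamed. Windows, combined clusters and cluster-free stretches named beside the shared stretches were chosen after their values were seen, by rank.

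The scripts were tested on simulated lists. Planted copies of clusters of replicate 1 (5477 clusters), moved by less than their width, were all found (100%). An offset of 0.15 added to every X score was recovered as 0.15. Both outcomes were fixed by construction, so they check the code and not the power of the methods. The 5412 clusters of replicate 2 were also placed at random to make 20 lists. Of these lists, 0 gave a p at or under 0.05 for overlap with replicate 1, with fewer shifts than in the main test. Random placement lacks the clumping of the real lists, so this does not check the test on clumped lists.

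The comparisons by gene and by annotation feature that had been planned were not made. The gene table used here has coordinates of Release 6, the lists are in release 5, and positions were not converted between builds. Clusters could therefore not be assigned to genes, promoters, exons or introns, and gene lists were not tested. The tests, the naming rule and the first set of alternatives were fixed before the data were examined. Alternatives were a stricter selection by score (2739 clusters of replicate 1 and 2706 of replicate 2), other overlap rules, random placement in 100 draws, leaving out each replicate, the combined list, and arms trimmed to the part with clusters. Added after the data were seen were clusters of at least 3 kb, joining of clusters over gaps of up to 1 kb, shifts of 50 to 500 kb only, shifts by class of cluster width, the share of bases in clusters of at least 10 kb, and the X score difference with its alternatives.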

Results

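Heads of wild-type Oregon-R fruit flies (Drosophila melanogaster), with the stage given as mixed adult, were profiled for H3K36me1, the monomethylated form of a lysine in the tail of histone H3, by chromatin immunoprecipitation and sequencing (ChIP-seq). There were 2 ChIP replicates and 2 input replicates. An input is chromatin sequenced without antibody selection, and each input served the ChIP library of the same replicate number. Each ChIP replicate had its own list of enriched clusters, and a further list combined the replicates. Replicate 1 held 5477 clusters over 29.6 Mb, replicate 2 held 5412 clusters over 28.6 Mb and the combined list held 7567 clusters over 39.9 Mb. The read depth behind each list is unknown, since the lists hold positions and scores and no counts. The labels do not say that the replicates came from separate cages or collections, so the spread between their lists may be technical. The p-values come from shifting positions or permuting clusters and windows of these lists. None of them measures variation between replicates.

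H3K36me1 clusters covered 24.2% ± 0.598 (SD, n = 2) of the 6 assembled arms, 2L, 2R, 3L, 3R, 4 and X. Most clusters were short, with a median width of 2683 bases in replicate 1 and 2628 bases in replicate 2. The widest spanned 127.3 kb in replicate 1 and 108.4 kb in replicate 2. Clusters of at least 10 kb made up 12.3% ± 0.364 (SD, n = 2) of the clusters and held 48.2% ± 0.826 (SD, n = 2) of the covered bases. That share, examined after the data were seen, depends on how clusters are delimited: it was 63.0% when clusters were joined over gaps of up to 1 kb. Within each list, wider clusters carried higher scores, with a Spearman correlation across clusters of 0.749 in replicate 1 and 0.784 in replicate 2. Clusters are not independent replicates, and the score is the authors' own value per cluster, whose definition is not given in the sources used here.

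The first comparison asked how far the replicates placed H3K36me1 in the same regions. Of the 5477 clusters of replicate 1, 4339 (79.2%, Wilson 95% interval 78.1 to 80.3) shared at least 1 base with a cluster of replicate 2. In the other direction 4510 of 5412 clusters did (83.3%, interval 82.3 to 84.3). These intervals cover counting error over clusters only. Every cluster of at least 10 kb was found in the other list, 688 in replicate 1 and 652 in replicate 2. Wide clusters are also hit more often by chance, and shifts of the other list met 56.2% and 56.5% of them on average. Among clusters narrower than 2 kb, 53.7% of replicate 1 and 59.5% of replicate 2 were found, against 29.3% and 30.4% by shift. Clusters without a partner had a median width of 1603 bases in replicate 1, against 3342 bases for those with one. In replicate 2 these medians were 1569 and 3191 bases. Unpartnered clusters also had lower median scores, 0.605 against 0.738 in replicate 1 and 0.536 against 0.684 in replicate 2. In bases, 25.3 Mb lay in both lists and 33.0 Mb in either, a Jaccard index of 76.5%. When the other list was shifted along each arm, the shared percentage averaged 36.3 over both directions and 1000 shifts, and no shift exceeded 45.7. The 1-sided permutation p was 0.001 in each direction, the smallest that 1000 shifts can give. The observed percentages were 2.20 and 2.28 times the shifted means.

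The 10 widest stretches shared by both replicates lay on 3L (4 stretches), 2L (2), 3R (2), 2R (1) and X (1), and none lay on chromosome 4. They ran from 70.5 to 108.3 kb and together spanned 0.838 Mb, or 3.32% of the shared bases. The widest, 3L:10300705-10408976 in FlyBase release 5 coordinates, measured 108.3 kb and scored 1.72 in replicate 1 and 1.61 in replicate 2. A stretch near the telomeric end of 3L (3L:749160-826546, 77.4 kb) belonged to the top-scoring cluster of each replicate list, at 2.01 and 1.95. On 2L the widest shared stretches were 2L:14490657-14589027 (98.4 kb) and 2L:7892727-7966703 (74.0 kb). On X the stretch was X:19247498-19332164 (84.7 kb), with scores of 1.44 and 1.36. On 2R it was 2R:14172952-14243499 (70.5 kb), with scores of 1.73 and 1.57. A further stretch on 3L, 3L:5178031-5270058, measured 92.0 kb, and 3R:5700262-5774710 measured 74.4 kb with scores of 1.78 and 1.62. In both replicates all 10 parent clusters scored at or above the 95.4th percentile of their list.

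The replicates set the ends of some of these stretches differently. The cluster over 3L:11359458-11446754 (87.3 kb shared) ran on to 127.3 kb in replicate 1 and stopped at 87.6 kb in replicate 2. The cluster over 3R:6336449-6407663 (71.2 kb shared) measured 71.2 kb in replicate 1, 103.8 kb in replicate 2 and 129.0 kb in the combined list. The genes in these stretches are not named, because the gene table used here has coordinates of another assembly than the cluster lists.

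**Figure D1:**
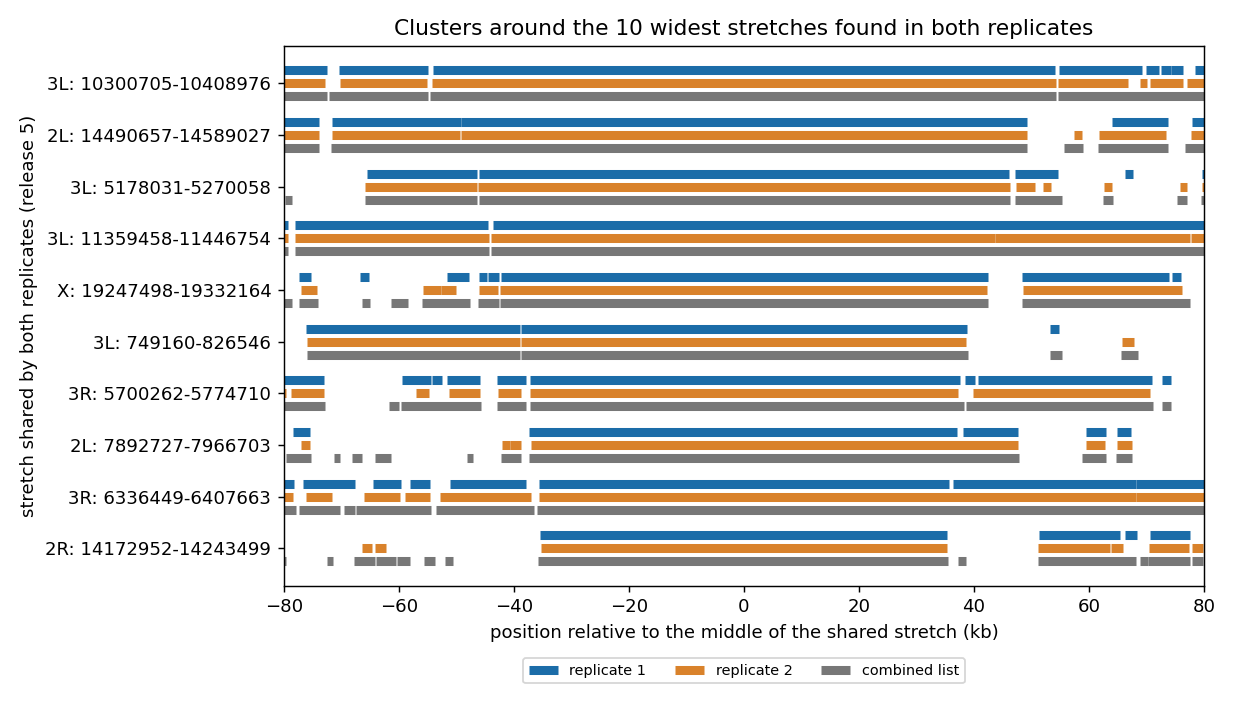
Clusters of replicate 1, replicate 2 and the combined list around the 10 widest shared stretches, drawn as bars by position in kb from the middle of each stretch, with 80 kb shown on each side. The bars nearly coincide for the widest stretch (108.3 kb in replicate 1 and 108.4 kb in replicate 2), while the cluster at 3R:6336449-6407663 runs further in replicate 2 (103.8 kb) than in replicate 1 (71.2 kb).

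The combined list was then set against the lists of the replicates it draws on, so no test of independence applied. It contained nearly every region that the replicates shared: 39 shared bases of 25.3 Mb lay outside it. It touched 99.6% of the clusters of replicate 1 and 99.9% of those of replicate 2. In turn, 63.4% of its bases lay in both replicate lists, 74.0% lay in replicate 1 and 71.7% lay in replicate 2. The remaining 7.04 Mb (17.7%) lay in neither. Counted as clusters, 3303 (43.7%) touched both replicates, 874 touched replicate 1 only, 728 touched replicate 2 only and 2662 (35.2%) touched neither. Clusters touching both replicates had a median width of 5824 bases and a median score of 0.625. Those touching replicate 1 only had medians of 2036 bases and 0.407, and those touching replicate 2 only had 1990 bases and 0.394. Clusters touching neither had medians of 1311 bases and 0.394, narrower than the single-replicate clusters at a similar score. Of those 2662 clusters, 1312 (49.3%) were narrower than the narrowest cluster of the replicate lists, which was 1302 bases in replicate 1 and 1301 bases in replicate 2. The combined list itself began at 1001 bases.

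Across the genome, H3K36me1 clusters covered the large euchromatic arms at similar levels and were sparse on chromosome 4 and on the heterochromatic scaffolds. Coverage was 23.7% ± 0.729 on 2L, 22.7% ± 0.363 on 2R, 26.5% ± 0.512 on 3L and 23.6% ± 0.711 on 3R (SD, n = 2 each). On X it was 25.5% in replicate 1 and 24.5% in replicate 2. Chromosome 4, a small chromosome rich in heterochromatin, was covered to 11.9% ± 1.01 (SD, n = 2), which was 0.455 of the level of the large autosomal arms in replicate 1 and 0.531 in replicate 2. The mapped heterochromatic scaffolds were covered to 0.538% ± 0.136 (SD, n = 2), against 24.1% ± 0.588 for the large autosomal arms. They held 19 clusters in replicate 1 and 18 in replicate 2, and neither replicate listed a cluster on 2LHet, XHet or YHet. The combined list held 2 clusters on 2LHet and 1 on XHet. The ratio of scaffold to autosomal coverage, 0.0223 in the replicate mean, was 0.0389 in the combined list, 0.0119 in the upper-scoring part of the lists and 0.0144 with clusters of at least 3 kb. With so few arms no test between them was made. The percentages use full sequence lengths, with no allowance for repeated sequence in which short reads cannot be placed. The low values on the scaffolds and chromosome 4 therefore do not separate such sequence from absence of the mark.

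X and the autosomal arms differed little in covered length, with a ratio of 1.04 in replicate 1 and 1.03 in replicate 2, and X lay within the range of the autosomal arms in both replicate lists. In the combined list the ratio was 1.10 and X, covered to 35.9%, lay above each autosomal arm, of which 3L was highest at 35.2%. With the upper-scoring parts of the replicate lists alone (2739 and 2706 clusters), the mean ratio of X to the autosomal arms was 1.27. Clusters on X scored higher, as given below, so a cut at the median score of each list keeps more of them by construction. This ratio is therefore no separate evidence of wider coverage on X. Clusters were more frequent on X, at 50.8 ± 1.77 per Mb against 44.0 ± 0.0586 per Mb on the large autosomal arms (SD, n = 2).

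Coverage also varied along each arm, in the same places in both replicates. The most covered 1 Mb windows were at 10 to 11 Mb of 3L (57.0% in replicate 1 and 56.0% in replicate 2), at 0 to 1 Mb of 3L (49.0% and 48.2%) and at 14 to 15 Mb of 2L (44.0% and 42.5%). Away from the centromeric ends, the least covered were 10 to 11 Mb of 2L (7.74% and 6.81%), 2 to 3 Mb of 3R (7.97% and 7.41%) and 11 to 12 Mb of 3R (8.19% and 8.66%). Over the 117 full windows of the 5 large arms, coverage in the replicates correlated with a Pearson r of 0.989 and a Spearman rho of 0.983. The 2-sided permutation p was 1e-05 for each, the smallest that 100000 permutations can give. The median absolute difference between replicates was 1.09 percentage points and the largest was 5.41. Windows are neighbouring parts of the same genome and not independent replicates.

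**Figure D2:**
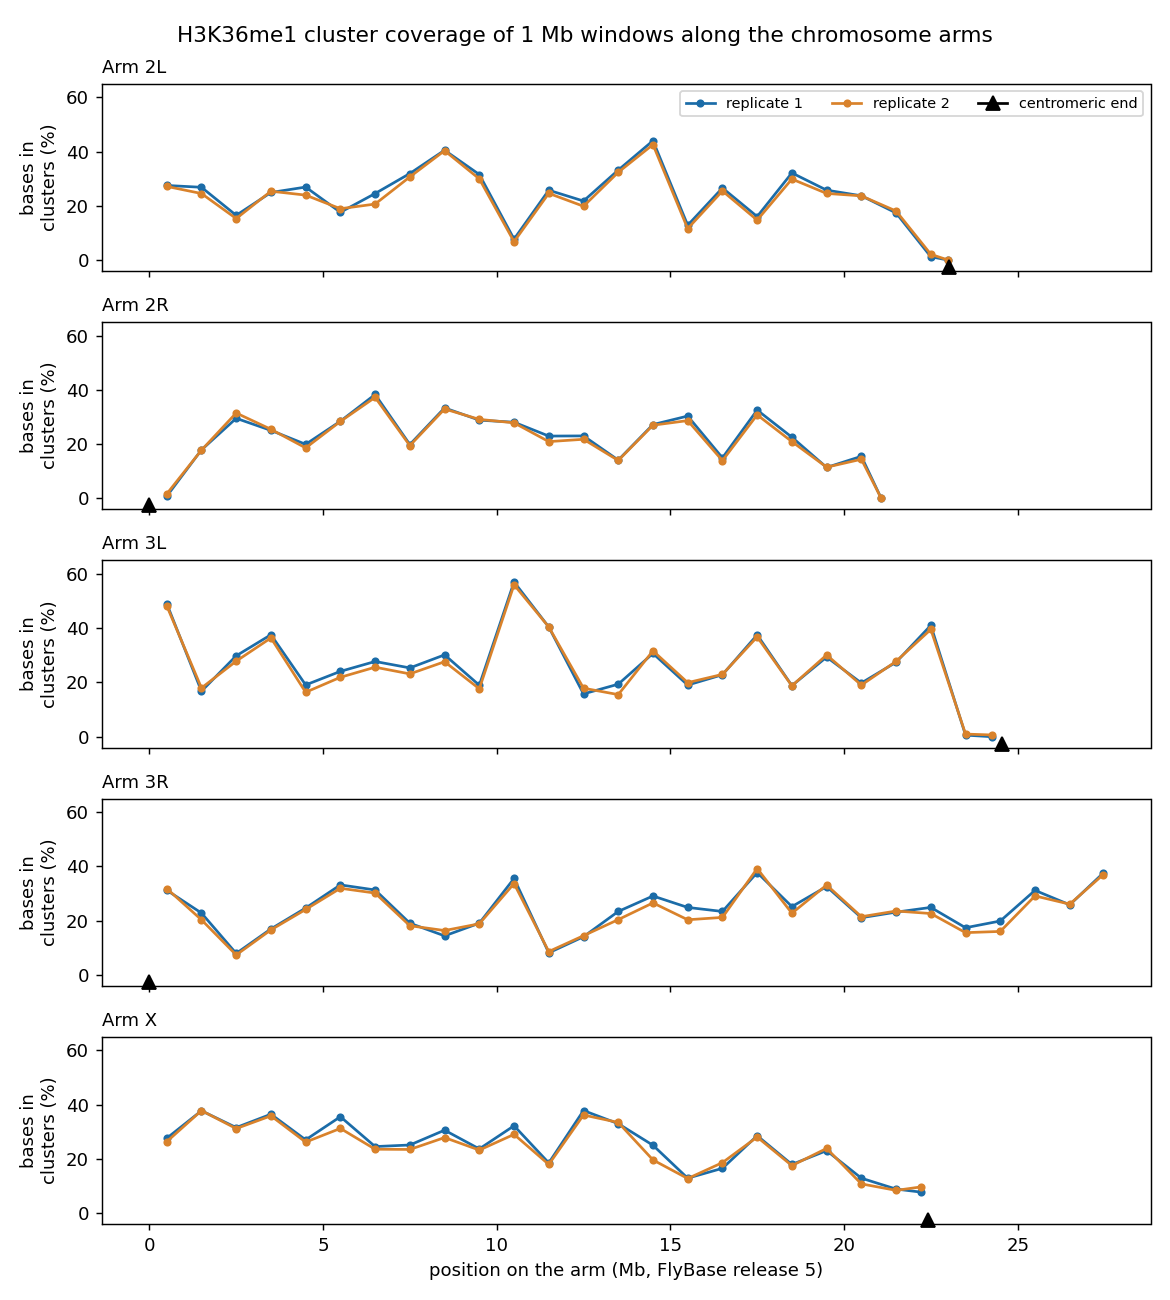
Percentage of bases in H3K36me1 clusters (vertical axis) in successive 1 Mb windows along arms 2L, 2R, 3L, 3R and X (position in Mb, release 5) for replicate 1 and replicate 2, where triangles mark the centromeric ends and the last window of each arm is shorter than 1 Mb. The replicates follow each other along every arm, with the peak at 10 to 11 Mb of 3L (57.0% and 56.0%) and low values at the centromeric ends of 2L, 2R, 3L and X.

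Clusters on X carried higher scores than those on the autosomal arms in all 3 lists, a comparison chosen after the data were seen. The median score was 0.846 on X against 0.659 on the large autosomal arms in replicate 1, and 0.773 against 0.616 in replicate 2. The autosomal arms ranged from 0.650 to 0.668 in replicate 1 and from 0.609 to 0.621 in replicate 2, so the gap to X exceeded the spread among them. The difference was 0.187 in replicate 1, 0.157 in replicate 2 and 0.119 in the combined list. X clusters were not wider, with medians of 2540 bases against 2733 bases in replicate 1. When the X label was permuted over 1 Mb windows, the 2-sided permutation p was 1e-05 in each list, the smallest that 100000 permutations can give. All X windows lie on a single chromosome, so this p does not weigh X against the spread between arms. With so few arms, no test between arms was made. The combined list draws on the libraries of the replicates and is no separate evidence. Among the upper-scoring parts of the replicate lists, a selection made on the score itself, the difference averaged over both replicates was -0.000154.

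**Figure D3:**
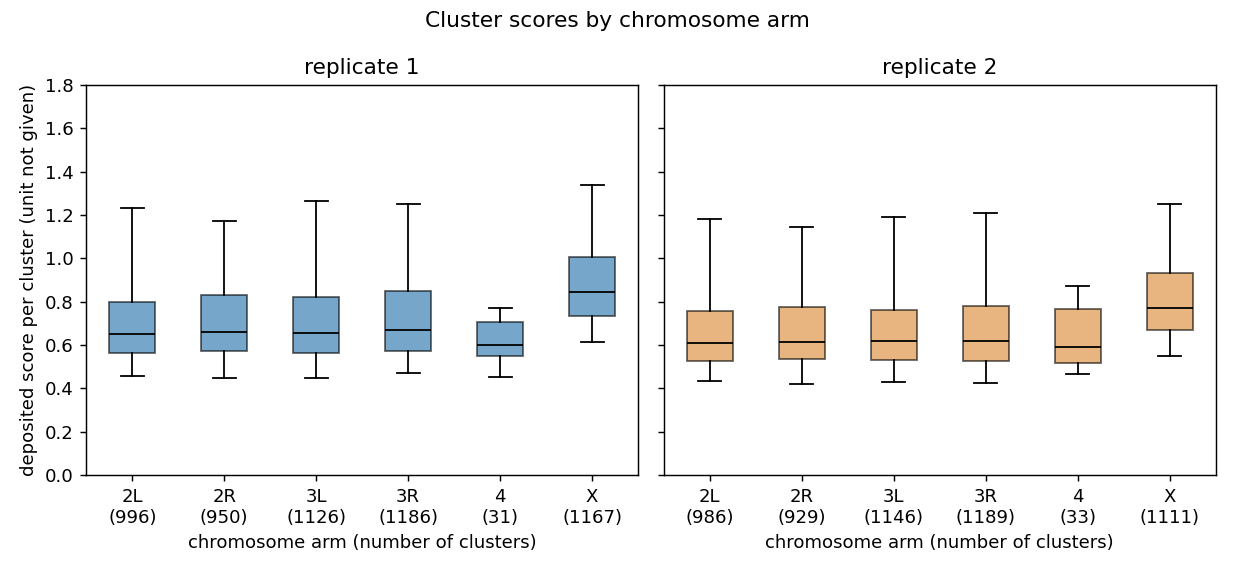
Deposited score per cluster (unit not given) by chromosome arm in replicate 1 and replicate 2, with boxes for the quartiles, lines for the medians, whiskers from the 5th to the 95th percentile and the number of clusters under each arm. X stands above the other arms, with medians of 0.846 and 0.773 against 0.659 and 0.616 for the large autosomal arms.

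The last comparison asked whether the regions that scored high in replicate 1 also did so in replicate 2. Scores of the 2875 pairs of clusters that overlapped one to one correlated with a Pearson r of 0.920 and a Spearman rho of 0.848 across clusters. These pairs hold only part of the 5477 and 5412 clusters of the replicates. Clusters without a partner, which scored lower, and those that overlapped several clusters of the other list did not enter. Pairs on X and on the autosomal arms were pooled. The 2-sided permutation p was 1e-05 for each, the smallest that 100000 permutations can give. Clusters are not independent replicates, and score rose with width in each list.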

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

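The share of bases in clusters of at least 10 kb, the minimum of 3 kb, the joining over gaps, the shift of 50 to 500 kb, the shifts by width class and every alternative for the X score difference were tests chosen after the results were seen. The mean percentage of clusters found in the other replicate kept its direction and its side of the threshold under each alternative but the void minimum of 1 kb, from 61.2 with reciprocal 50% overlap (6.10 by random placement) to 86.2 with clusters of at least 3 kb (30.5 by shift). Shifts of 50 to 500 kb gave 37.6, against 36.3 for shifts over the whole arm. The score correlation ranged from 0.918 to 0.929 under 3 of its alternatives. With a single replicate, the share of the combined list covered ranged from 71.7% to 74.0%, by construction above the 63.4% in both. The covered ratio of X to the autosomal arms was 1.27 in the upper-scoring part, which favours X by construction because its scores were higher. This ratio was 1.00 with clusters of at least 3 kb, 1.10 in the combined list and 1.03 on trimmed arms. The chromosome 4 ratio was 0.417 in the upper-scoring part and 0.626 on trimmed arms. The X score difference was kept under 6 alternatives (0.119 to 0.187), of which several could not go against it. Windows of 2 Mb change only the p, leaving out a replicate gives the value of the other, and the combined list draws on the same libraries. With clusters of at least 3 kb and after joining, the difference was 0.169 each. In the upper-scoring part, where clusters were selected on the score itself, the X score difference was -0.000154 as the mean of the replicates (larger permutation p = 0.93). That mean does not give the difference in each replicate. The share of bases in clusters of at least 10 kb, 48.2%, was 51.9% in the combined list, 60.5% in the upper-scoring part, 60.0% with clusters of at least 3 kb and 63.0% after joining. The minimum of 3 kb raises this share by construction, since it removes only narrower clusters. Joining makes clusters wider, and the upper-scoring part favours wide clusters, since score rose with width. The cause of the other shifts was not tested. The minimum of 1 kb, set in advance, removed 0 clusters. No paired analysis was possible because the inputs entered no comparison and the ChIP replicates form a single group. The alternatives set in advance for features, genes, gene lists, gene positions and gene length were not run, for lack of annotation in release 5. Depth is unknown, so whether narrow unshared clusters reflect it cannot be examined.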

Other observations

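All tests below, on the X scores, the arm ends and the cluster-free stretches, were chosen after those patterns had been seen in the data, and those of the density of clusters on X and of the 95th percentile were added after the results of the first tests. The test of unplaceable sequence in the cluster-free stretches was redefined after its first result had been seen. Its first form also counted combined clusters that only reached over an edge of a stretch, which fixed its outcome. Long stretches inside the arms held no H3K36me1 cluster in either replicate. More than 2 Mb from the centromeric ends, 119 such stretches of at least 100 kb summed to 18.0 Mb, with 33 on 3R, 32 on 2L and 18 each on 2R, 3L and X. The longest were X:19955394-20323824 (368.4 kb), 3R:12457306-12814235 (356.9 kb), 3L:1949401-2284190 (334.8 kb), 3R:2418519-2738693 (320.2 kb) and 2L:5463795-5725140 (261.3 kb). The combined list covered 2.23% of these bases.

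Coverage also fell off at most centromeric ends. The last 1 Mb on the centromeric side was covered to 1.70% ± 0.632 on 2L, 1.24% ± 0.593 on 2R, 0.247% ± 0.349 on 3L and 4.57% ± 0.633 on X (SD, n = 2 each). Arm 3R differed, with 31.6% ± 0.432 in its centromeric 1 Mb and 35.9% ± 0.698 in its telomeric 1 Mb.

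The higher scores on X were not due to wider clusters, since within 10 classes of width at least 0.927 of the difference was kept. A higher calling floor on X alone stays open. Above a score that X clusters pass, X held at least 1.57 times as many clusters per Mb (interval in that replicate 1.31 to 1.91). A floor would leave equal numbers only if the arms were otherwise equally dense in clusters, which was not tested. The difference among the widest clusters (those from 5532 bases in replicate 1) was at least 0.821 of that among the narrowest (up to 1734 bases). Its lowest bound, 0.518, only just met the criterion against a floor. The difference was smaller at the 95th percentile of the scores (0.0969 and 0.0697) than at the 5th (0.156 and 0.122), as a floor could give. In the upper-scoring part it averaged -0.000154. A few regions were not the source, as 100% of the 23 windows of X lay above the autosomal median in both replicates. A single constant offset stays open, since a test whose criterion was written before its own value was seen, though after the X pattern had been found, did not exclude 0 in either replicate (change from the narrowest to the widest clusters -0.0322, interval -0.0887 to 0.0208, and -0.0126, interval -0.0651 to 0.0370), while one added later went against it (difference at the 95th percentile minus that at the median -0.0902 and -0.0875, both intervals below 0) but depends also on the mix of widths on X, which it does not hold fixed. How the score treats the copy number of X in flies of unknown sex may also contribute, and no biological explanation was tested because the samples are not separated by sex.

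The sparse centromeric ends of 2L, 2R, 3L and X are not what an edge effect of assembled sequences would give, since the telomeric 1 Mb, averaged over these arms, was covered 19.1 times as much in replicate 1 and 12.3 times in replicate 2, with the lowest single ratio on X in replicate 2 (5.26). Repeated sequence in which short reads cannot be placed could also leave such ends without clusters. The combined list covered 4.33% of these ends on average, a value that does not separate repeats from absence of the mark. That would need the release 5 sequence, so these cannot be told apart, and no biological explanation was tested.

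The cluster-free stretches outnumbered those of independent placement. The regions covered by either replicate, placed at random within each arm, gave at most 15 stretches in 100 draws, against 119. Such placement also breaks up clusters that lie close together, so it does not tell how many stretches close neighbours alone would leave. Most of the cluster-free stretches were not wholly closed to short reads, since 78.2% (93 stretches) held a whole cluster of the combined list clear of both edges, or 77.3% without the 4 top-scoring clusters of that list. For the other 26, which include 3R:12457306-12814235, and for parts of the rest, such sequence may still contribute. No biological explanation was tested, as the genes in these stretches could not be named.

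The top 4 scores of the combined list belonged to clusters about 1 kb wide that shared no base with either replicate list: 2R:16264151-16265163 and U:9487796-9488861 (3.21 each), 3R:16095571-16096629 (2.42) and 2R:222139-223145 (2.07). Lower in the ranking, 3R:1276063-1277299 (1.84, 1237 bases wide) and X:13895131-13896131 (1.69, 1001 bases wide) also shared no base with either replicate list. The other clusters ranked between the top 4 and the latter overlapped both replicate lists. How the combined list was scored is not given in the sources used here, so the scores of the unshared clusters cannot be read as strong H3K36me1.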
